A study of Homo sapiens with 12 samples.

How the data were processed

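RNA of 12 libraries was sequenced by the authors. Per the labels' protocols, the human mantle cell lymphoma lines Granta-519 and JeKo-1 were infected with lentivirus carrying an shRNA against cyclin D1 (shCycD1) or a control shRNA (shCtrl) and selected with puromycin. Total RNA was extracted with an RNeasy kit, and libraries were made with a stranded mRNA kit. Each of the 4 groups holds 3 libraries, which the series design calls biological replicates. Groups and replicate numbers were taken from the sample titles.

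The authors deposited 1 table of gene values per cell line, with 25368 rows for Granta-519 and 25370 for JeKo-1, of which 92 in each are ERCC spike-in RNAs (synthetic transcripts added to a sample). The submitters' processing notes name FastQC, TopHat2 2.1.1, limma 3.9 and the human builds GRCh37 and hg19, with no role or order. The read counter, the gene annotation, any filter and the log transform are not given in the sources used here. Per the file headers, the tables carry sample names only, and the deposited files are titled as RPKM (reads per kilobase and 1000000 reads).

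The deposited values were read as the natural log of RPKM + 1. For Granta-519 this was tested on the values. Low values of genes shorter than 5000 bases, taken out of a natural log and multiplied by the gene's genomic span (introns included), were whole multiples of a single step in each library in 81.7 to 83.7% of cases, within a tolerance of 0.1. Chance gives 20%. Base 2 gave 53.7 to 58.7% and base 10 gave 47.0 to 50.6%. For JeKo-1 the log base is inferred and not settled. No base gave more than 38.7% whole values there, with smaller steps searched than for Granta-519. Spike-in values were compared by the SD of their logs, JeKo-1 over Granta-519, for all 36 pairs of libraries. With the natural log this ratio had a median of 0.97 (0.92 to 1.01), against 0.70 with base 2 and 2.17 with base 10. It assumes the same spike-in mix in both lines. JeKo-1 values times the longest transcript summed to 1453600 to 1501600 per library with the natural log. The gene length behind the JeKo-1 values was not the genomic span and is compatible with an exonic length. Because the tables use different lengths, the median log2 ratio of Granta-519 to JeKo-1 went from 1.75 to -1.58 over octiles of span relative to transcript length, so levels were never compared between the tables. If the JeKo-1 table were log2, most of its changes would be smaller. Under that reading the counts, the lists of JeKo-1 and of the difference, 4 lists of the average and the named genes that could be tested were recomputed.

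Values were taken out of the log to RPKM, and 1 row was used for each gene symbol, the row with the highest mean. This left 23617 symbols in Granta-519 and 23615 in JeKo-1, a choice made after the tables had been seen. Of these, 554 symbols in each table stand on more than 1 row. Gene names were used as the files give them, and no coordinates are given. For span, transcript length and GC content, symbols were matched to reference tables of the later build GRCh38, with a transcript for 89.2% of 23800 symbols.

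Each line was fitted alone with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend) on log2(RPKM + 0.5), for genes at an RPKM of 1 or more in at least 3 of the 6 libraries of the line. This kept 12668 genes in Granta-519 and 11866 in JeKo-1. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes, and errors given with them are standard errors (SE). Benjamini-Hochberg adjusted p under 0.05 was called. For 10653 genes that passed in both tables, a joint fit of the 12 libraries with a mean for each of the 4 groups gave the average of both changes and their difference (Granta-519 minus JeKo-1). Overlap of calls was tested with Fisher's exact test, one-sided. A design clause for files already in log2 was not used, since the values are not log2.

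Fixed before the data were examined were 24 gene lists, the tests, and most alternatives. The lists cover D-type cyclins, cyclin-dependent kinases (CDK), their inhibitors and the RB family; DNA replication and G1/S; mitosis and G2/M; DNA damage signalling and homologous recombination; p53 targets; the BCL2 family; type I interferon response; NF-kappaB targets; ribosome biogenesis and MYC targets; B-cell identity; plasma cell differentiation; MHC and antigen presentation; homing and adhesion; unfolded protein and amino acid stress; cholesterol and fatty acid synthesis; hypoxia and glycolysis; oxidative phosphorylation; cytoplasmic ribosomal proteins; replication-dependent histones; mitochondrially encoded transcripts; immediate early and heat shock genes; and markers of T and NK cells, myeloid cells, and epithelial, fibroblast and embryonic kidney cells. Lists with at least 3 measured members were tested with camera (limma) at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma), which asks whether the genes of a list move on balance one way and does not compare them with other genes. Mitochondrially encoded transcripts had 0 measured members in either line and were not analysed here.

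Named genes followed a rule fixed in advance. It takes 10 fixed genes; in each line, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap; up to 4 members of each list with the smallest adjusted p; and, over both lines, the 10 risen and 10 fallen genes with the smallest adjusted p and the 10 with the smallest adjusted p for the difference. Many of the largest changes were genes of microRNAs and other short RNAs, so the same ranking without them is also given, a choice made after their values were seen, as was naming SSX4B. Some genes that the rule takes are not reported here.

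The scripts were tested on simulated data with 200 changed genes. Changes of 0.5, 1 and 2 (log2) were recovered in 23.9, 91.0 and 97.0% of cases in Granta-519 over 12464 genes, and in 42.4, 87.9 and 97.0% in JeKo-1 over 11637 genes. Unchanged genes made up 2.76 and 3.85% of the calls. For the average over both lines the shares recovered were 78.8, 98.5 and 97.0% over 10455 genes, with 5.73% unchanged genes among the calls. For the difference, 0 of 10455 genes were called with no simulated difference. No true difference was simulated, so recovery of differences was not tested. Noise was drawn independently for each gene, and few genes changed. In the real data 40.6% (Granta-519) to 66.3% (average over both lines) of genes were called, so these rates may not carry over.

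If 1 step is 1 read, the Granta-519 values correspond to about 30715985 to 41080978 reads per library. The step was taken as the largest whose share of whole values lay within 3 percentage points of the best, a rule set after a smaller step, with about equal fit, had been found for shCycD1 replicate 1, so that library's number is uncertain by a factor of 2. The values times span sum to 8079285 to 8326930 per library, not to 1000000, and this scale is unexplained. A depth taken from the step by the definition of RPKM would be lower, so the depth of every Granta-519 library is uncertain. For JeKo-1 the depth is unknown. Alternatives were another pseudocount, filter, scaling, variance model or pairing, and leaving out each library. Added after seeing the data were spike-in scaling, a GC correction (lowess span 0.3), leaving out short RNA genes or symbols on several rows, and the JeKo-1 table read as log2. Figures were drawn with matplotlib 3.10.9.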

Results

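The effect of silencing cyclin D1 on gene expression was measured in Granta-519 and JeKo-1, lines of mantle cell lymphoma, a B-cell lymphoma in which the cyclin D1 gene CCND1 is typically switched on by a translocation. Each line had 3 libraries with an shRNA against CCND1 (shCycD1) and 3 with a control shRNA (shCtrl). Libraries of a group correlated at r of 0.98 to 0.99 in Granta-519 and 0.97 in JeKo-1, and libraries of different groups at 0.95 to 0.96 and 0.88 to 0.90 (log2 values across genes). Taking 1 step of the values as 1 read, depth was about 30715985 to 41080978 reads per library in Granta-519 (1 of the 6 being uncertain by a further factor of 2). The unexplained scale of these values leaves the depth of all 6 uncertain. In JeKo-1 the depth is unknown. The comparisons ask which genes follow the loss of cyclin D1 in each line, which in both, and which differ between the lines.

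CCND1 was lower in every silenced library of both lines. In Granta-519 it went from 947 ± 87.2 RPKM (SD, n = 3) in shCtrl to 268 ± 47.3 in shCycD1, a log2 change of -1.83 ± 0.14 (SE, adjusted p = 0.000257). The shCtrl libraries stood at 924, 1044 and 874 RPKM and the shCycD1 libraries at 213, 298 and 292. In JeKo-1 it went from 347 ± 42.3 to 65.9 ± 1.39 RPKM, a log2 change of -2.38 ± 0.09 (adjusted p = 1.96e-06), with shCtrl libraries at 395, 330 and 315 RPKM and shCycD1 libraries at 65.4, 64.8 and 67.4. The difference between the lines was 0.55 ± 0.18 (adjusted p = 0.0306). Its call was lost with quantile normalization (0.38, adjusted p = 0.0886) and with the JeKo-1 table read as log2 (-0.16, adjusted p = 0.486). It was also lost without Granta-519 shCtrl 1 (0.53) or 3 (0.49), shCycD1 2 (0.46) or 3 (0.48), or JeKo-1 shCtrl 1 (0.45), shCycD1 1 (0.54) or 2 (0.53), over alternatives with adjusted p of 0.00367 to 0.486. With spike-in scaling it was 1.43 (adjusted p = 0.00554), with CCND1 at -1.08 in Granta-519.

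**Figure D1:**
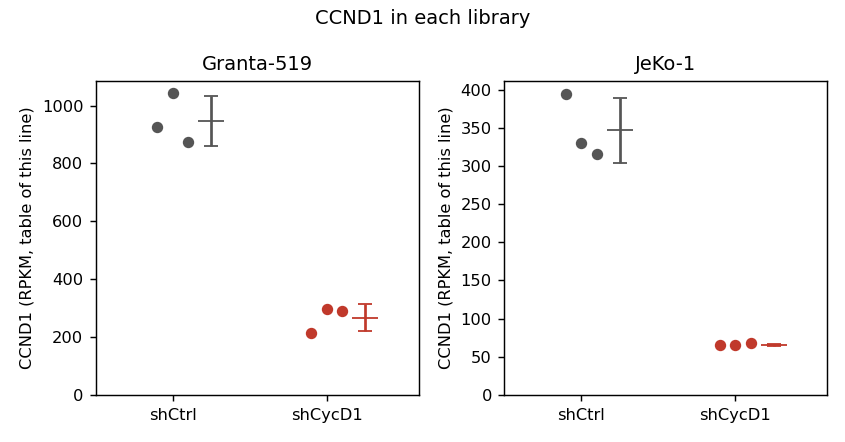
CCND1 in RPKM (vertical axis from 0, each line on the scale of its own table) in the 3 shCtrl and 3 shCycD1 libraries of Granta-519 and JeKo-1; points are libraries and the bar beside them is mean ± SD. Every shCycD1 library lay below every shCtrl library, at 213 to 298 RPKM in Granta-519 and 64.8 to 67.4 in JeKo-1.

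Among the other D-type cyclins, CCND2 rose in Granta-519 from 1.33 ± 0.12 to 5.25 ± 0.93 RPKM (log2 change 1.64 ± 0.13, adjusted p = 0.000268). In JeKo-1 it stood at 0.13 and 0.84 RPKM, under the minimum for testing. CCND3 fell by 0.27 in Granta-519 (adjusted p = 0.0431). That call was lost without a low-value filter (adjusted p = 0.0636), with quantile normalization (adjusted p = 0.0504) and with the replicate number as a block (adjusted p = 0.103). It was also lost without any 1 of the 6 libraries (values of -0.31 to -0.23). In JeKo-1 CCND3 rose by 0.53 (adjusted p = 0.00449), a call lost with the GC correction (0.20, adjusted p = 0.132) or spike-in scaling. CDK4, the kinase partner of these cyclins, fell by 0.40 (adjusted p = 0.00677) and by 0.43 (adjusted p = 0.000996), and the JeKo-1 call was lost with quantile normalization (adjusted p = 0.0510) and spike-in scaling (adjusted p = 0.247), the value being -0.68 with the GC correction. CDK6 was at -0.41 in Granta-519 without passing the test (adjusted p = 0.0844) and was not tested in JeKo-1. It was called lower with quantile normalization (-0.49, adjusted p = 0.0287), with library weights (-0.54, adjusted p = 0.00323) and without shCtrl 2 (-0.54, adjusted p = 0.0302), over alternatives with adjusted p of 0.00323 to 0.669. The CDK inhibitor gene CDKN1A fell by 0.52 in Granta-519 and by 1.79 in JeKo-1. CDKN1B was at -0.0011 in Granta-519 (adjusted p = 0.996) and rose by 0.61 in JeKo-1 (adjusted p = 0.0063), a call lost with spike-in scaling (adjusted p = 0.245). E2F1, a transcription factor of S-phase entry, fell by 1.42 (-0.68 with spike-in scaling) and by 1.95. MYC rose by 1.27 in JeKo-1 (adjusted p = 0.00314) and was at 0.10 in Granta-519 (adjusted p = 0.603). SOX11, a marker of mantle cell lymphoma, fell by 0.67 in JeKo-1 (adjusted p = 0.00107) and by 0.43 in Granta-519 (adjusted p = 0.036), the latter call being lost without the filter (adjusted p = 0.0626) and without shCtrl 1 or 3 (-0.47 and -0.33) or shCycD1 1 or 2 (-0.45 and -0.33). With spike-in scaling, which moved the median of all Granta-519 genes to 0.72, CCND3, CDK4, CDK6, CDKN1A and SOX11 stood above 0 in that line and were not called, and MYC and CDKN1B were called higher. Of the list of D-type cyclins, CDKs, inhibitors and RB family, 3 of 27 measured members rose and 15 fell in Granta-519 (3 and 15 adjusted over the list alone), and 7 of 26 rose and 16 fell in JeKo-1 (8 and 17 adjusted over the list alone). This list also holds the cyclin E genes, the E2F genes and CCND1, so the silencing of the target itself counts in it. CDC25A, a phosphatase that activates CDKs, fell by 1.10 and by 2.78, and E2F8 fell by 1.57 and by 3.60. The list was called lower in both lines (camera, adjusted p = 0.000134 and 0.00559), with adjusted p = 0.205 and 0.211 with an estimated correlation. With spike-in scaling, which moved the median of all genes to 0.72, the Granta-519 median was 0.23 and the list was still called lower against other genes (adjusted p = 7.83e-05). The JeKo-1 median of -0.69 was -0.43 without the filter.

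Genes of DNA replication and of mitosis fell together in Granta-519. Of 61 measured members of the DNA replication and G1/S list, 60 fell and 0 rose (60 adjusted over the list alone), with a median log2 change of -1.19. ASF1B, a histone chaperone, fell by 1.52, the ribonucleotide reductase subunit RRM1 fell by 1.30, DUT fell by 1.13 and the flap endonuclease FEN1 fell by 1.10. All 94 measured members of the mitosis list fell (94 adjusted over the list alone), with a median of -1.31; BIRC5 fell by 1.52, the cyclin CCNB1 fell by 1.38, the kinase AURKB fell by 1.37 and the spindle factor TPX2 fell by 1.34. Of 42 genes of DNA damage signalling and homologous recombination, 35 fell (36 adjusted over the list alone), with a median of -0.83, among them CHEK1 (-1.25), RAD54L (-1.22) and EXO1 (-1.27). The camera test called the 3 lists lower (adjusted p = 2.23e-30, 2.01e-41 and 2.11e-13). With an estimated correlation none was called (adjusted p = 0.205, 0.205 and 0.252). With spike-in scaling, which moved the median of all genes to 0.72, 12 replication genes fell and 1 rose (median -0.46), 29 of the 94 mitosis genes fell (median -0.60), and 1 DNA damage and recombination gene fell and 5 rose (median -0.15).

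Replication-dependent histone genes rose in Granta-519 while replication genes fell. Of 36 measured histone genes 22 rose and 5 fell (22 and 6 adjusted over the list alone), with a median of 1.14, or 0.68 without the filter. HIST1H1C, a linker histone, went from 200 ± 5.69 to 1437 ± 118 RPKM (log2 change 2.84 ± 0.08, adjusted p = 6.08e-05), HIST1H2BD rose by 2.21, HIST2H2BE rose by 2.64 and HIST1H4H rose by 3.02. HIST1H3B and HIST1H4B fell by 2.16 and by 1.83. The list was called higher (camera, adjusted p = 0.000134), but not with an estimated correlation (adjusted p = 0.197). Histone genes are near copies of each other, so values of single members are uncertain.

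Lists of interferon, NF-kappaB, homing and MHC genes leaned higher in Granta-519, with 13, 15, 11 and 4 members not called either way. Of 32 type I interferon genes 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.37; MX1 rose by 1.80, OAS1 rose by 1.57, EPSTI1 rose by 1.18 and OAS2 rose by 0.89. Of 31 NF-kappaB targets 14 rose and 2 fell (17 and 2 adjusted over the list alone; median 0.40), among them the adhesion gene ICAM1 (1.19), the chemokine receptor CCR7 (1.73), CD83 (1.48) and EBI3 (1.27). Of 25 homing and adhesion genes 11 rose and 3 fell (11 and 3 adjusted over the list alone; median 0.37), including VCAM1 (2.17), CD44 (1.23) and RGS1 (1.65). Of 22 MHC and antigen presentation genes 15 rose and 3 fell (16 and 3 adjusted over the list alone; median 0.36), with HLA-DQA1 at 0.79. HLA-DOA, HLA-DQB1 and HLA-DMA were at 0.81, 0.69 and 0.71 but stand on several rows, and the list's call was lost without such symbols, where fewer members enter (median 0.28, 2 risen, adjusted p = 0.139). The homing call was lost without the filter (adjusted p = 0.0563), with library weights (adjusted p = 0.0741), without symbols on several rows (adjusted p = 0.0583) and without shCycD1 replicate 2 (adjusted p = 0.0826). Camera called these 4 lists higher (adjusted p = 0.000347, 0.000733, 0.0359 and 0.0012). With an estimated correlation none was called (adjusted p = 0.252, 0.405, 0.519 and 0.252).

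In Granta-519 the lipid, ribosome biogenesis and B-cell lists leaned lower, with 13, 33 and 16 members not called either way. Of 30 cholesterol and fatty acid genes 16 fell and 1 rose (18 and 1 adjusted over the list alone; median -0.39); FADS1 fell by 1.31, SREBF1 fell by 0.94, EBP fell by 0.76 and TM7SF2 rose by 0.87. Of 52 ribosome biogenesis and MYC targets 19 fell (15 adjusted over the list alone; median -0.19), among them PAICS (-0.82), FBL (-0.72), LDHA (-0.70) and PA2G4 (-0.48). Of 34 B-cell identity genes 14 fell and 4 rose (16 and 5 adjusted over the list alone; median -0.21); VPREB3 fell by 1.0 and TCL1A fell by 1.06, while FCER2 rose by 0.72 and CD37 rose by 0.39. Camera called these 3 lists lower (adjusted p = 3.34e-05, 0.000134 and 0.0171), and none with an estimated correlation (adjusted p = 0.519, 0.205 and 0.519). With spike-in scaling, which moved the median of all genes to 0.72, the medians of these 3 lists were 0.34, 0.55 and 0.50. The cholesterol and fatty acid list was still called lower against other genes (adjusted p = 0.00107), and the other calls were lost (adjusted p = 0.135 and 0.177). The members called with it were 5 risen cholesterol and fatty acid genes, 22 risen ribosome biogenesis genes and 12 risen B-cell genes, with 0 fallen.

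The remaining lists were not called by camera in Granta-519. Their medians were -0.06 for p53 targets (3 rose and 10 fell of 33; 4 and 10 adjusted over the list alone, the basis of each later count marked alone), 0.17 for the BCL2 family (4 and 3 of 15; 4 and 3 alone), 0.20 for plasma cell genes (8 and 3 of 20; 8 and 3 alone), 0.13 for protein and amino acid stress (13 and 4 of 32; 13 and 4 alone), 0.17 for hypoxia and glycolysis (10 and 7 of 32; 11 and 7 alone), 0.02 for oxidative phosphorylation (5 and 2 of 53; 4 and 2 alone), 0.13 for ribosomal proteins (6 and 1 of 70; 1 and 0 alone) and -0.04 for early and heat shock genes (5 and 2 of 27; 1 and 0 alone). The early and heat shock list had a mean of 0.11 against its negative median. With single libraries left out, medians near 0 moved to -0.14 to -0.07 for p53 targets, -0.0030 to 0.11 for oxidative phosphorylation and -0.09 to 0.07 for early and heat shock genes, and spike-in scaling put them at 0.69, 0.76 and 0.70. Of T and NK cell markers 3 were measured, with 2 fallen (LCK at -1.15), of myeloid markers 6 with 3 risen (FCER1G at 0.69), and of epithelial, fibroblast and kidney cell markers 9 with 3 risen and 1 fallen (TAGLN at 0.69), with equal counts adjusted over the list alone. Ribosomal proteins were called higher with spike-in scaling, quantile normalization, library weights, a mean RPKM of 5 or more, and without shCtrl 2 or shCycD1 2 (medians of 0.22 and 0.19), the stress list with spike-in scaling (adjusted p = 0.0194) and a mean RPKM of 5 or more (adjusted p = 0.0260), and T and NK markers lower with quantile normalization (adjusted p = 0.0484) and without shCycD1 1 or 2 (medians of -0.47 and -0.62). The fry test, which does not compare a list with other genes, called 17 of the 23 lists in this line, 12 of them called by camera. Of the remaining lists it called the BCL2 family (adjusted p = 0.00237), stress (adjusted p = 0.00197), plasma cell genes (adjusted p = 0.0329) and myeloid markers (adjusted p = 0.00853) higher. It called T and NK markers lower (adjusted p = 0.00526). Members named by the rule include BMF, a pro-apoptotic gene (1.45), SLAMF7 (1.47), CHAC1 (1.47), DNAJB9 (1.31), BTG2 (0.66) and JUN (1.09).

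In all, 2840 genes rose and 2303 fell in Granta-519 out of 12668 tested (limma, adjusted p under 0.05), and 383 and 380 with an absolute log2 change of 1 or more. The 3 libraries of a group did not overlap those of the other in 54.0% of genes, where chance gives 10%. These changes are relative to the other genes of a library: scaling by the spike-ins moved the median of all genes from 0.03 to 0.72 and gave 7331 risen and 157 fallen genes. Against that median of 0.72 the mitosis list was at -0.60, the histone list at 1.83 (25 risen and 2 fallen) and the interferon list at 1.09 (26 risen and 0 fallen). The risen members of the NF-kappaB list were then 26, of the homing list 18, of oxidative phosphorylation 39 and of ribosomal proteins 68. Of the 129 named and tested genes of this line 20 lost their call with that scaling and 14 changed sign.

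The 10 largest rises in Granta-519 were led by genes of short RNAs: MIR27A, RNU6-78, MIRLET7A1 and MIR4695 were listed at 0 in every shCtrl library, and MIR146A went from 12 ± 7.63 to 192 ± 27.3 RPKM (log2 change 4.10 ± 0.37, adjusted p = 0.000407). MIR22 and MIR24-2 were at 4.55 and 3.91. These values stand on few reads: the 4 genes at 0 in shCtrl had means of about 1.3 (MIR4695) to 4.7 (RNU6-78) recovered reads per shCycD1 library, MIR24-2 had 4.3 and MIR22 had 11.3, against 77.4 for MIR146A. The other 3 were NEUROD2 (3.57 ± 0.24), HIST1H2AC (3.39 ± 0.22) and the chemokine CCL19 (3.17 ± 0.23). All 10 of the largest falls were short RNA genes, of which MIR4745, MIR4667, SNORD124, MIR367, SNORD1B and SNORD105B were listed at 0 in every shCycD1 library, and MIR3687, SNORD62A, MIR4747 and MIR1178 were at -3.82, -3.08, -2.85 and -2.57. The 6 genes at 0 in shCycD1 had means of about 1.0 (SNORD1B, SNORD105B) to 3.0 (MIR4745) recovered reads per shCtrl library, and SNORD62A, MIR4747 and MIR1178 had 3.7, 4.0 and 2.3. Without such genes the largest rises also held HIST1H3H (2.95), SPATA31D1 (2.82), HIST1H2BC (2.73) and HIST2H2AA3 (2.61), and the largest falls, after HIST1H3B, CCND1 and HIST1H4B, were ITPRIPL1 (-1.67), KIAA0754 (-1.64), TMSB15A (-1.59), UBE2C (-1.58), GINS2 (-1.57), E2F8 and TK1 (-1.57). Without the filter the calls of SNORD62A, MIR4747, MIR1178 and KIAA0754 were lost. SNORD62A was also lost without any 1 library other than shCycD1 1, and MIR4747 without any 1 shCtrl library. MIR1178 was lost without shCtrl 1 or 3 or shCycD1 2 or 3, and KIAA0754 without shCtrl 1 or 3 or shCycD1 1 or 3. The MIR22 call was lost with library weights (2.25, adjusted p = 0.0771) and without shCycD1 1 (4.37, adjusted p = 0.0563).

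The same cell cycle groups fell in JeKo-1. Of 62 replication and G1/S genes 61 fell (61 adjusted over the list alone), with a median of -2.21; the thymidylate synthase gene TYMS fell by 3.51, RRM2 fell by 3.83 and GINS2 fell by 3.23. All 93 measured mitosis genes fell (93 adjusted over the list alone), with a median of -3.13, among them HMGB2 (-3.58), TOP2A (-4.01), NUSAP1 (-3.65) and KIF2C (-3.29). Of 42 DNA damage and recombination genes 35 fell and 2 rose (37 and 2 adjusted over the list alone; median -1.56), with CHEK1 at -3.20 and FANCI at -2.63. Camera called the 3 lists lower (adjusted p = 3.13e-29, 6.93e-41 and 3.74e-13), and none with an estimated correlation (adjusted p = 0.211 for each). In this line the change of a gene went with its GC content (Spearman rho 0.40 across genes, which are not independent; 0.03 in Granta-519). The deviations of single libraries had rho of -0.14, -0.43 and -0.51 in shCtrl and 0.49, 0.34 and 0.30 in shCycD1. With that trend removed, the medians of the 3 lists were -2.33, -3.02 and -1.64.

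Interferon genes rose in JeKo-1. Of 41 measured 39 rose and 1 fell (40 and 1 adjusted over the list alone), with a median of 2.17, or 2.02 with the GC trend removed. IFI27 went from 0.67 ± 0.13 to 16.3 ± 2.61 RPKM (log2 change 3.84 ± 0.14, adjusted p = 1.55e-06), MX1 rose by 3.25, OAS1 rose by 2.78 and the signalling factor IRF9 rose by 2.45. Of 22 MHC and antigen presentation genes 20 rose (20 adjusted over the list alone), with a median of 0.96, or 0.82 with the GC trend removed. HLA-DQA1 rose by 1.19, while HLA-DPA1, HLA-DMB and HLA-DQB1 were at 1.49, 1.28 and 1.80 and stand on several rows. Camera called both lists higher (adjusted p = 3.74e-13 and 2.53e-06), with adjusted p = 0.211 and 0.385 with an estimated correlation. The MHC call was lost without symbols on several rows (adjusted p = 0.0750), where fewer members enter and the median was 1.19 with 4 risen.

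Histone genes fell on balance in JeKo-1, with 6 of 35 risen and 16 fallen (6 and 16 adjusted over the list alone; median -0.46, or -0.84 with the GC trend removed). HIST1H3C fell by 2.44, HIST1H3F fell by 1.52 and HIST1H2BJ fell by 1.40, while HIST1H3H rose by 1.73. Of 53 oxidative phosphorylation genes 30 fell and 4 rose (30 and 4 adjusted over the list alone; median -0.31), with NDUFB6 at -1.23, COX7B at -0.95, ATP5H at -0.61 and COX7C at 0.88. Of 52 ribosome biogenesis and MYC targets 29 fell and 4 rose (29 and 4 adjusted over the list alone; median -0.28, or -0.43 with the GC trend removed), with LDHA at -1.37, FBL at -1.08, PAICS at -0.94 and LYAR at -0.90. Of 70 ribosomal protein genes 32 rose and 8 fell (32 and 7 adjusted over the list alone; median 0.20), with RPL13A at 1.13, RPLP1 at 0.81 and RPLP0 at 0.77. Camera called the first 3 lists lower (adjusted p = 0.0212, 0.000196 and 0.000104) and ribosomal proteins higher (adjusted p = 0.0215). None was called with an estimated correlation (adjusted p = 0.564, 0.630, 0.211 and 0.809). The histone call was lost with the JeKo-1 table read as log2 (adjusted p = 0.119) and at a mean RPKM of 5 or more (adjusted p = 0.696), the oxidative phosphorylation and ribosome biogenesis calls with spike-in scaling (adjusted p = 0.0874 and 0.0576), and the former with quantile normalization (adjusted p = 0.0862). The ribosomal protein call was lost with the GC correction (adjusted p = 0.114), every other scaling tried, no filter, and without shCtrl 3, shCycD1 1 or shCycD1 2 (medians of 0.14, 0.17 and 0.20).

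The remaining lists were not called by camera in JeKo-1. Their medians were -0.12 for p53 targets (9 rose and 10 fell of 28; 9 and 12 adjusted over the list alone, the basis of each later count marked alone), 0.54 for the BCL2 family (10 and 1 of 15; 10 and 2 alone), 0.44 for NF-kappaB targets (6 and 0 of 28; 5 and 0 alone), 0.38 for B-cell identity (21 and 6 of 36; 21 and 6 alone), -0.11 for plasma cell genes (6 and 7 of 16; 6 and 7 alone), 0.43 for homing and adhesion (12 and 3 of 22; 12 and 3 alone), 0.01 for protein and amino acid stress (13 and 13 of 31; 13 and 13 alone), -0.16 for cholesterol and fatty acid synthesis (8 and 12 of 29; 8 and 12 alone), 0.02 for hypoxia and glycolysis (13 and 12 of 32; 13 and 13 alone) and 0.34 for early and heat shock genes (9 and 4 of 26; 9 and 4 alone). The p53 list had a mean of 0.07 against its negative median and a camera test pointing down, and the stress and hypoxia lists had positive medians with a camera test pointing down. The fry test pointed up for these 3 lists without calling them (adjusted p = 0.193, 0.397 and 0.141). It called 15 of 22 lists in this line, 10 of them called by camera. Of the remaining lists it called the BCL2 family (adjusted p = 0.00047), B-cell identity (adjusted p = 0.00167) and homing (adjusted p = 0.000678) higher. It called T and NK markers (adjusted p = 0.00047) and myeloid markers (adjusted p = 0.0243) lower. Of T and NK cell markers 7 were measured, with 2 risen and 5 fallen (LCK at -1.87, CD7 at 0.79), of myeloid markers 3 with 1 fallen (TYROBP at -0.90), and of epithelial, fibroblast and kidney cell markers 2, both risen (KRT8 at 0.35), too few for a list test, with equal counts adjusted over the list alone. The B-cell and BCL2 lists were called higher with quantile normalization (adjusted p = 0.0112 and 0.0388), the B-cell list also without shCycD1 3 (median 0.40), NF-kappaB targets without shCtrl 1 (median 0.71, against 0.12 without shCtrl 2 and 0.26 without shCycD1 1), and T and NK markers lower without the filter (-0.24, adjusted p = 0.0109). With the GC trend removed the medians were 0.22 for the B-cell list (16 risen and 11 fallen), 0.33 for the BCL2 family and 0.18 for NF-kappaB targets. They were -0.03 for early and heat shock genes (-0.06 at a mean RPKM of 5 or more) and -1.02 for T and NK markers. The calls of CD7 (0.13), KRT8 (0.03) and TAGLN (0.06) were then lost. Those of KRT8 and TAGLN were also lost with quantile normalization and spike-in scaling. Over all alternatives, medians near 0 ranged from -0.25 to -0.08 for p53 targets, -0.27 to 0.05 for plasma cell genes, -0.11 to 0.15 for stress, -0.29 to -0.07 for cholesterol and fatty acid synthesis and -0.13 to 0.06 for hypoxia. Named members include BMF (1.75), BIK (2.04), the B-cell genes FCER2 (2.28), BCL6 (1.68), CD38 (1.62) and PIK3CD (1.11), CD27 (-1.62), IRF1 (1.71), BTG2 (2.0), DDIT4 (2.85), ALDOC (1.80), GAPDH (-0.99), MSMO1 (-1.17), DNAJA1 (-1.53) and FOS (1.53).

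**Figure D2:**
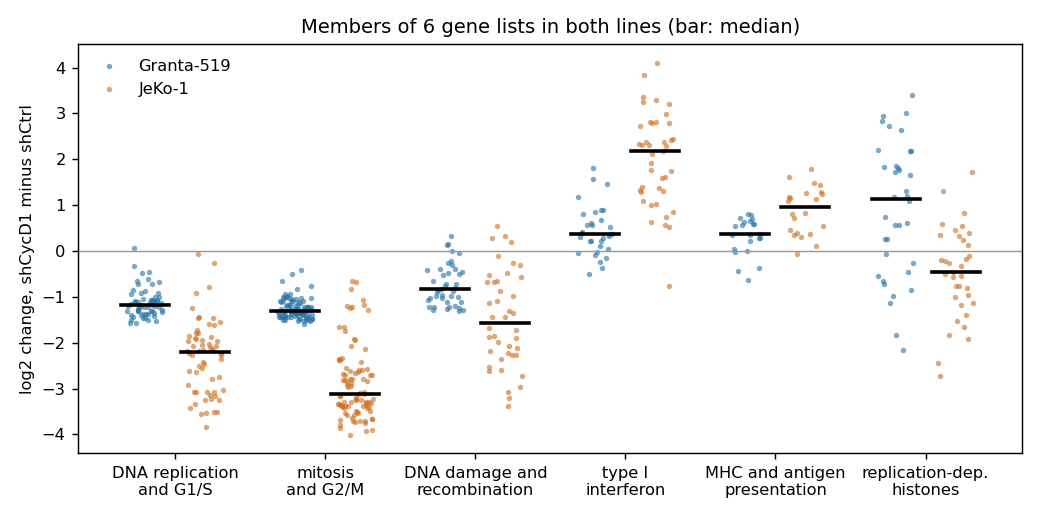
Log2 change (shCycD1 minus shCtrl, vertical axis) of each measured member of 6 gene lists in Granta-519 and JeKo-1; points are genes and black bars are medians. The mitosis medians were -1.31 and -3.13, the interferon medians 0.37 and 2.17, and the histone medians 1.14 and -0.46.

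In all, 4357 genes rose and 3303 fell in JeKo-1 out of 11866 tested, and 1087 and 828 with an absolute log2 change of 1 or more. Groups did not overlap in 69.6% of genes, where chance gives 10%. With spike-in scaling 1697 rose and 1788 fell, with 60 fallen replication genes, 91 fallen mitosis genes and 36 risen interferon genes, but 11 risen MHC genes, 10 fallen ribosome biogenesis genes, 5 fallen oxidative phosphorylation genes and 1 risen ribosomal protein gene. The spike-ins of this line differed by a median of 0.13 with an interquartile range of 0.49, and did not move together.

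**Figure D3:**
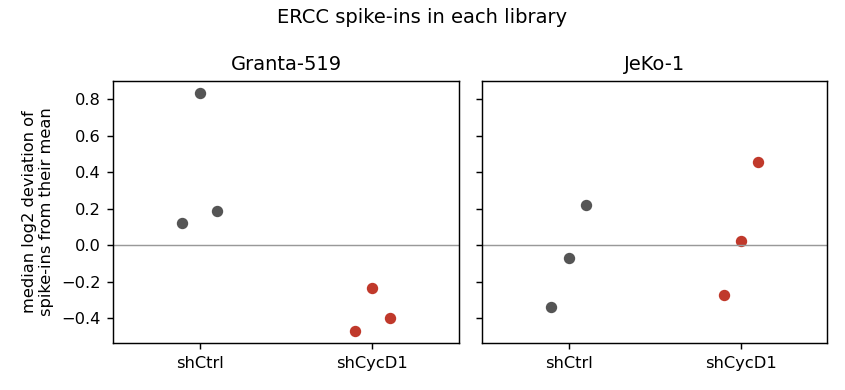
Median log2 deviation of the spike-ins from their mean (vertical axis) in the 3 shCtrl and 3 shCycD1 libraries of each line; points are libraries. In Granta-519 the shCycD1 libraries lay at -0.47 to -0.24, below all shCtrl libraries, and in JeKo-1 the groups overlapped.

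Among the 10 largest rises in JeKo-1, MIR3687, SNORD49A, MIR647, MIR181B1, SNORD103B and MIR5193 were listed at 0 in every shCtrl library, SNORD103B standing on several rows. The read numbers behind short RNA genes are unknown in this line, so these values are uncertain. MIR3687 was among the largest falls in Granta-519. MIR941-2, MIR339 and MIR1909 were at 5.79, 5.64 and 5.58, the MIR1909 call being lost without shCtrl 3 (4.53, adjusted p = 0.0520). The remaining gene was APOD, a lipid carrier, which went from 0.30 ± 0.06 to 47.8 ± 12.5 RPKM (log2 change 5.88 ± 0.18, adjusted p = 8.64e-07). Without short RNA genes the list went on with IFIT3 (4.11), RGS1 (4.06), IFI27, PIK3IP1 (3.57), the MYC antagonist MXD4 (3.46), EIF4EBP3 (3.45), LOC100507254 (3.45), MYL4 (3.42) and TNFRSF14 (3.39). The largest falls held SNORD88C, listed at 0 in every shCycD1 library, MIR3918 (-4.31) and SNORD21 (-4.20). The calls of MIR3918 and SNORD21 were lost without the filter and with some single libraries left out. Then came TOP2A, FAM111B (-3.99), CDK1 (-3.94), NCAPG (-3.90), PBK (-3.86) and RRM2, followed without short RNA genes by MKI67 (-3.80), AURKB (-3.74) and NUF2 (-3.74). SSX4 had the largest fall, from 119 ± 14.1 to 0.00101 RPKM, but stands on several rows, and its near copy SSX4B, named after its values were seen, was at 17.3 ± 11 and 31.2 ± 1.98 RPKM, so the value is uncertain.

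Averaged over both lines, cell cycle genes led the falls. Of 10653 genes tested in both, 3940 rose and 3123 fell. The 10 fallen genes with the smallest adjusted p were NCAPH (average log2 change -2.37 ± 0.05), NUSAP1 (-2.51), HJURP (-2.40), HMGB2 (-2.53), KIF2C (-2.39), CHEK1 (-2.22), PLK4 (-2.23), CCNA2 (-2.58), TPX2 (-2.35) and ZWINT (-2.34). The 10 risen were the receptor gene TNFRSF14 (2.32 ± 0.05), the actin regulator CTTN (2.24), PBXIP1 (2.25), APOD (3.88), SYNPO (2.34), MXD4 (2.60), the kinase DYRK1B (2.18), PIK3IP1 (2.49), MVP (1.58) and MX1 (2.53). Mitosis genes had a median of -2.23 (93 of 93 fell), replication genes -1.69 (61 of 61 fell) and interferon genes 1.0 (29 of 31 rose and 1 fell), with equal counts adjusted over the list alone. Camera called these 3 lists (adjusted p = 1.94e-44, 2.08e-32 and 6.8e-10), and none with an estimated correlation (adjusted p = 0.0807, 0.0807 and 0.0822). For the average camera called 12 of 20 lists, and 0 with an estimated correlation. Also lower were DNA damage and recombination, ribosome biogenesis, cholesterol and fatty acid synthesis, and oxidative phosphorylation. The list of D-type cyclins, CDKs, inhibitors and RB family, which holds CCND1 itself, was called lower too (17 of 25 fell and 6 rose). Of its D-type cyclins, CCND3 was at 0.13 on average and not called. Also higher were MHC, NF-kappaB, homing and ribosomal protein genes. Histones were not called (camera, adjusted p = 0.0925). With spike-in scaling 4204 genes rose and 775 fell on average.

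Calls of the single lines overlapped. Of genes tested in both, 1573 rose in both lines where 825.8 were expected of independent lists (odds ratio 5.91, one-sided Fisher's exact p = 3.37e-286), and 1397 fell in both where 586 were expected (odds ratio 8.95). In opposite directions, 121 rose in Granta-519 and fell in JeKo-1, and 198 did the reverse. Changes correlated across genes with Pearson's r of 0.56 and Spearman's rho of 0.56; genes are not independent replicates. With spike-in scaling 1188 rose and 85 fell in both.

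**Figure D4:**
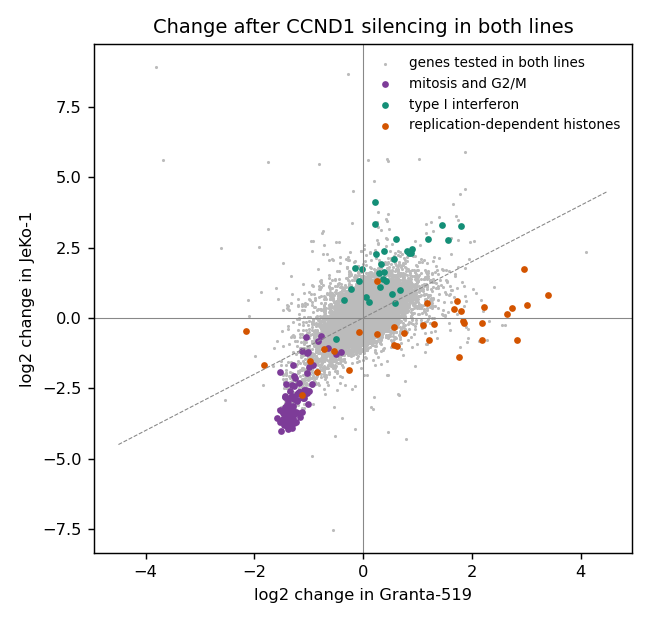
Log2 change in Granta-519 (horizontal axis) against JeKo-1 (vertical axis) for genes tested in both lines, with the mitosis, interferon and histone lists in colour; points are genes and the dashed line marks equal change. Across genes Pearson's r was 0.56, and the mitosis genes lay below the dashed line.

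The change differed between the lines for 4463 genes, 2053 higher and 2410 lower in Granta-519 than in JeKo-1. The 10 with the smallest adjusted p were HIST1H1C (2.84 in Granta-519 and -0.80 in JeKo-1, difference 3.64 ± 0.12, adjusted p = 3.63e-08), the tyrosine kinase FGR (0.65 and -2.75), NUSAP1 (-1.37 and -3.65), LIMK1 (0.12 and 2.31), TNFRSF14 (1.25 and 3.39), FMO1 (-0.83 and 1.75), HIST1H2BJ (1.76 and -1.40), CTTN (1.15 and 3.32), NCAPH (-1.45 and -3.29) and C3orf37 (-0.27 and 2.06). The mitosis list differed by a median of 1.79 (86 of 93 members called), the replication list by 1.14 (55 of 61, with 1 the other way), the interferon list by -1.43 (27 of 31) and the histone list by 1.53 (23 of 34, with 1 the other way). Adjusted over the list alone these counts were 86, 57 (1 the other way), 27 (1) and 25 (2). Camera called all 4 (adjusted p = 1.6e-40, 9.98e-25, 4.96e-13 and 3.53e-11). With an estimated correlation only the histone list was called of these 4 (adjusted p = 0.0596, 0.0993, 0.0596 and 0.0401). With the JeKo-1 table read as log2 the medians were 0.94, 0.49, -0.88 and 1.46. With spike-in scaling 3985 genes were higher and 143 lower in Granta-519, and the medians of the 4 lists were 2.62, 1.96, -0.59 (9 interferon genes lower and 1 higher) and 2.32, with all 4 still called by camera.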

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

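The tests of the short RNA genes, of the silencing shRNA, of the CCND1 loss and of the replication list were chosen after their values had been seen. So were spike-in scaling, the GC correction and the reading of JeKo-1 as log2. For the log base and the replication list, the bound of 0.3 in place of 0.5 was also settled after the value had been seen.

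Effects that differed between the lines (test of the difference, Granta-519 minus JeKo-1) covered 9 gene lists. Medians were 1.14 for replication and G1/S, 1.79 for mitosis, 0.68 for DNA damage and recombination, -1.43 for interferon, -0.67 for B-cell identity, -0.47 for MHC and antigen presentation, -0.45 for cholesterol and fatty acid synthesis, 0.31 for oxidative phosphorylation and 1.53 for histones. With an estimated correlation only the histone list was called (adjusted p = 0.0401). With JeKo-1 read as log2 camera called the 9 lists, with medians of 0.24 for DNA damage and -0.22 for MHC. The call was lost for oxidative phosphorylation with quantile normalization (0.14), for MHC without symbols on several rows (-0.39) and for cholesterol with library weights (-0.30) and spike-in scaling (0.42). Cholesterol was at -0.26 without Granta-519 shCtrl 3, still called. Spike-in scaling also put B-cell identity at 0.17 and MHC at 0.40 with the shift of all genes, both still called lower against other genes. Some lists were called by camera only under an alternative. These were ribosome biogenesis with the GC correction (0.24, adjusted p = 0.0133) and without JeKo-1 shCtrl 2 (0.14, adjusted p = 0.0488). The BCL2 family was called without the filter (-0.36, adjusted p = 0.0469). The list of D-type cyclins, CDKs, inhibitors and RB family was called with spike-in scaling (0.91, adjusted p = 0.0452). Single genes that differed were HIST1H1C (3.64), FGR (3.4), NUSAP1 (2.28), LIMK1 (-2.19), TNFRSF14 (-2.14), FMO1 (-2.58), HIST1H2BJ (3.16), CTTN (-2.17), NCAPH (1.84) and C3orf37 (-2.34), and of the fixed genes CCND1 (0.55), CCND3 (-0.80), CDKN1A (1.27), CDKN1B (-0.61) and MYC (-1.18). With spike-in scaling CCND3 (-0.03), CDKN1B (0.26) and MYC (-0.30) were not called, and CDKN1B was also lost under the log2 reading (-0.44, adjusted p = 0.0834).

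The ERCC spike-ins, which enter only the spike-in scaling and the reading of the log base, were lower in the silenced libraries of Granta-519 by a median log2 of 0.75 (a difference of -0.75), with 43 of 53 spike-ins below every shCtrl library. The shCtrl libraries deviated by 0.12, 0.84 and 0.19 and the shCycD1 libraries by -0.47, -0.24 and -0.40. In JeKo-1 they differed by 0.13 (interquartile range 0.49), without a split between the groups. The labels do not say whether spike-ins were added per cell or per amount of RNA.

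Interferon genes rose more in JeKo-1 than in Granta-519. Removing the GC trend left their JeKo-1 median at 2.02 (1.94 to 2.09 with each library left out), which argues against that trend as the whole cause. Reading the JeKo-1 table as log2 left a difference of -0.88 (-0.93 to -0.80), against -1.43 in the main fit. This argues against the log base as the whole cause, but a part of the difference could come from it. Both groups carried an shRNA by lentivirus, so a response to the vector that both share would cancel in the change. Other effects of the silencing shRNA cannot be told apart from the loss of CCND1, since the labels name 1 silencing group per line. The same limit holds for the replication, mitosis and histone changes. Spike-in scaling, which moved the median of all genes from 0.03 to 0.72 in Granta-519 and from 0.09 to -0.03 in JeKo-1, gave -0.59 with 9 of 31 genes lower and 1 higher, still called lower against other genes (camera, adjusted p = 4.53e-22), and a biological difference between the lines stays open and untested.

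Replication and mitosis genes fell more in JeKo-1. With the GC trend removed the mitosis median stayed at -3.02 (-3.12 to -2.98), and with the table read as log2 the difference stayed at 0.94 (0.88 to 1.01), which argues against both as the whole cause for mitosis genes. For replication genes the GC correction left -2.33 (-2.39 to -2.30), which argues against that trend. Under the log2 reading the difference was 0.49 (0.44 to 0.58), with 41 genes higher and 1 lower (camera, adjusted p = 2.13e-13). That is above the 0.3 that the log base as the whole cause would allow, but short of the 0.5 set for this list. The bound of 0.3 was chosen after the value had been seen, so the log base is not decided for replication genes. A larger loss of CCND1 in JeKo-1 cannot be told apart from other differences between the lines: the CCND1 difference was 0.55, but -0.16 (adjusted p = 0.486) under the log2 reading and 1.43 with spike-in scaling, and there are 2 lines. A biological difference between the lines stays open and untested.

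Histone genes rose in Granta-519 and not in JeKo-1. Non-histone genes of short span (105 genes under 1000 bases) had a median of 0.019 (-0.08 to 0.06), and the summed RPKM of the list rose by 2.18 (2.16 to 2.21), from 614 to 637 in shCtrl libraries to 2734 to 2952 in shCycD1. These argue against a shift of all short genes, and against reads moving between copies within the list as the whole cause. HIST1H1C alone made up a large part of the shCycD1 sums. Copies outside the list were not summed, so reads moving in from them were not tested. Carry-over of RNA without poly(A) cannot be told apart: short RNA genes had a median of -0.12 (-0.24 to -0.09), but 322 of 481 had under 10 recovered reads per library. The summed values in JeKo-1 changed by -0.19, and a change in the tailing of histone transcripts, which usually lack poly(A), was not tested.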

How the results depend on the processing

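The log2 changes of CCND1 kept direction and call under every alternative run, at -1.92 to -1.08 in Granta-519 (adjusted p 2.99e-05 to 0.00319) and -2.53 to -1.67 in JeKo-1 (9.07e-12 to 3.58e-05). Spike-in scaling, the GC correction, leaving out short RNA genes or symbols on several rows, and the log2 reading were added after seeing the data. Requiring an absolute log2 change of 1 or more left 763 genes in Granta-519, 1915 in JeKo-1, 819 on average and 1030 for the difference, and a mean RPKM of 5 or more left 4488, 2903 and 1941 for the average, the difference and the overlap; fewer genes pass by construction. Spike-in scaling gave 3485 genes in JeKo-1 and an overlap of 1273. It also moved Granta-519 values of CCND3 (0.37), CDK4 (0.35), CDKN1A (0.23), CDKN1B (0.75) and SOX11 (0.31) above 0 with the shift of all genes to 0.72, and the medians of 4 of the 12 called lists there. The CCND1 difference was -0.16 under the log2 reading and 1.43 with spike-in scaling, the CDKN1B difference 0.26 with spike-in scaling, and the CDK4 difference, 0.03 and not called, was called at -0.27 with quantile normalization. Of 121 named and tested genes of JeKo-1 the log2 reading lost 0 calls and left 5 untested, and spike-in scaling lost 14. With an estimated correlation the calls of the replication and mitosis lists were lost at unchanged medians of -1.19 and -1.31 in Granta-519, -2.21 and -3.13 in JeKo-1, -1.69 and -2.23 on average and 1.14 and 1.79 for the difference; the estimate is made on few libraries.

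Leaving out each library in turn gave 3514 to 5216 genes in Granta-519, 6815 to 7434 in JeKo-1, 6662 to 7014 on average, 3725 to 4638 for the difference and 2195 to 2947 in the overlap. The Granta-519 calls of CCND3 and SOX11 were lost with single libraries left out (CCND3 at -0.31 to -0.23, SOX11 at -0.52 to -0.33), as were the differences of CCND1 (0.45 to 0.70) and CDKN1B (-0.73 to -0.50). Library weights gave 7614 genes in Granta-519; their fit over both lines, with 7468 genes on average and 5698 for the difference, stopped short of convergence. The causes were not tested.

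Libraries of the same replicate number correlated at 0.01, -0.12 and 0.03 in Granta-519 and at 0.19, 0.09 and 0.10 in JeKo-1 (deviations from group means). All 3 in Granta-519 and 1 of 3 in JeKo-1 lay under 0.1, so the numbers were not taken to pair the samples. With the replicate block 4188 genes were called in Granta-519, 8707 in JeKo-1, 7324 on average, 4795 for the difference and 2653 in the overlap. In JeKo-1 every library correlated best with its own number. The JeKo-1 spike-in deviations also went by number, at -0.34, -0.07 and 0.22 in shCtrl 1 to 3 and -0.27, 0.02 and 0.45 in shCycD1 1 to 3. Both are hints of pairing from the data, and pairing in JeKo-1 stays open. Of 129 named and tested genes of Granta-519 the block lost 7 calls, among them CCND3 (adjusted p = 0.103) and KIAA0754 (adjusted p = 0.0795). Depth was about 30715985 to 41080978 reads in Granta-519 if 1 step of the values is 1 read, and is uncertain by their unexplained scale. It is unknown in JeKo-1, where what it limits was not tested.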

Other observations

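Both lines shared genes outside the cell cycle lists that rose. MXD4 went from 13.1 ± 2.13 to 44.7 ± 3.59 RPKM in Granta-519 and from 4.89 ± 0.58 to 58.7 ± 4.07 in JeKo-1, PIK3IP1, an inhibitor of PI3 kinase, from 6.68 ± 1.0 to 18.4 ± 1.03 and from 1.48 ± 0.23 to 23.0 ± 3.06, and the pro-apoptotic BMF from 26.9 ± 4.13 to 73.7 ± 4.31 and from 6.54 ± 0.16 to 23.3 ± 3.09 (SD, n = 3). RGS1, a regulator of chemokine signalling, rose in both, from 94.6 ± 4.43 to 301 ± 60.3 and from 3.45 ± 0.32 to 66.4 ± 15.3.

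Other splits of the libraries were tested for the counts of called genes. Within a line there are 10 splits, too few for a share under 0.05: the real split, 1 of the 10, called 5143 genes in Granta-519 and 7660 in JeKo-1, and the highest of the others 6 and 5. Over both lines, 100 splits combine those of each line. Only the real one, 1 of 100, gave as many genes for the average (7063, highest other 4941). That is the smallest share that 100 splits can give, and it argues only against no effect in either line. An average carried mainly by 1 line is not excluded, since 4941 genes were called where only 1 line kept its real split. The real one was also alone in its count for the difference (4463, highest other 3864). Chance cannot be judged from these splits for the difference, since mixing the libraries of a line also removes an effect that both lines share. The highest others kept the real split of 1 line for the average and the difference. Where neither line kept it, at most 3 genes were called on average and 4 for the difference. The overlap was 2970 with the real split and at most 1 with others, but calls of the other splits limit their overlap to 6, so these splits say nothing of chance for it.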
